A study of Homo sapiens with 16 samples.

How the data were processed

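The series holds polyadenylated RNA sequencing of 2 human breast cancer cell lines and chromatin immunoprecipitation sequencing (ChIP-seq) labelled as MCF-7. MCF-7 is an oestrogen receptor positive line of luminal type, and MDA-MB-231 is an oestrogen receptor negative line of mesenchymal type. Per the labels, MCF-7 grew in DMEM with 10% serum and MDA-MB-231 in L-15 with 10% serum without CO2, so cell line and medium changed together. Each line was given DMSO, called untreated here, or JQ1, a small molecule that displaces BET proteins such as BRD4 from acetylated chromatin. JQ1 was given for 4 weeks. No duration is given for DMSO, so an effect of time in culture cannot be told apart from that of JQ1. There were 2 RNA libraries in each of the 4 groups and 1 ChIP library for each of 6 antibodies. Library groups were taken from the treatment and antibody given for each sample, or the title for the inputs, and the column of the untreated MCF-7 library without a tag in its title was assigned by elimination. Nothing in the labels says that the replicates come from separate cultures, so p-values measure only the spread between these libraries, which may be technical. All 8 RNA columns were used.

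The submitters' processing notes name fastp 0.19.6, STAR 2.4.0, HTSeq 0.12.4, Bowtie2, MACS2 and DESeq2, with GRCh38 (hg38) as genome build. The authors deposited gene expression as FPKM (fragments per kilobase of transcript, scaled to mapped fragments), 1 column per library, with 2 decimals. Which tool computed the FPKM, and with which gene models or filter, is not given in the sources used here. The peak lists hold 4 values per peak. As deposited by the authors, the score is 10 times -log10 of q as a whole number. The ratio, deposited by the authors as the signal value of MACS2, is the fold enrichment at the summit over the background the peak caller computed. The -log10 p and -log10 q values were computed by MACS2 and are used as deposited by the authors. The file names say that the BRD4, LSD1, MTA3 and H3K4me1 lists were called against input. Those labelled H3K27ac and RNAPol2 belong to separate samples whose file names do not mention an input. The input libraries have no peak lists and were not used here.

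The expression table had 18710 genes by Entrez ID, of which 98.3% (18384) had a symbol in the annotation, and 326 had none. FPKM summed to between 450890 and 488482 per library. FPKM values give no counts, so the depth of each library is unknown, and no counting interval or detection limit was computed for genes. The correlation between the 2 replicates of a group, across genes, was 0.985 and 0.986 in MCF-7 without and with JQ1 and 0.967 and 0.978 in MDA-MB-231. Replicate 1 minus 2 correlated with the annotated span of genes at a Spearman rho of -0.201 in untreated MDA-MB-231. It was 0.0900 there with JQ1, and -0.0443 and -0.0230 in MCF-7 without and with JQ1. The JQ1 effect had a rho of -0.114 with span in MDA-MB-231 and -0.0252 in MCF-7. The cause was not tested.

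Genes with a mean of at least 0.5 FPKM over the 8 libraries were tested (13219). FPKM were transformed to log2 after adding 1, which understates changes of genes with low values. One limma model (limma 3.58.1 in R 4.3.3) with a mean-variance trend was fitted to all 8 libraries, with 4 residual degrees of freedom. Contrasts were JQ1 against DMSO in each line, the difference of these effects (MDA-MB-231 minus MCF-7), and the untreated lines (MDA-MB-231 minus MCF-7). P-values were two-sided and adjusted by Benjamini-Hochberg over the genes tested, with 0.05 as threshold. The wording "rose", "fell", "higher" and "lower" refers to genes past it. In simulated data with 200 changed genes, each gene had 1 spread pooled over the 4 groups. With changes in MCF-7, the fit found 0% of 67 genes changed 1.5-fold, 13.4% of 67 changed 2-fold and 65.2% of 66 changed 4-fold. It made 2 false calls. With changes in MDA-MB-231 it found 1.49%, 29.9% and 69.7%, with 6 false calls. In the data 29.5% (MCF-7) and 28.0% (MDA-MB-231) of genes were past the threshold, a far larger share than was changed here. The Benjamini-Hochberg cutoff depends on that share, so these rates do not give the power of the tests reported below.

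Before the data were examined, 32 gene lists, the rule for naming genes and the alternatives were fixed, apart from the tests named as later choices. The lists covered BET-dependent oncogenes, HEXIM1 with polyadenylated histone genes, BET proteins with elongation factors, the LSD1, CoREST and NuRD complexes, genes of the study's topic, ABC transporters, drug metabolism, oestrogen response, luminal, mesenchymal and basal markers, DNA replication, mitosis, interferon-stimulated genes, NF-kB and inflammation, antigen presentation, cholesterol synthesis, fatty acids and lipid storage, hypoxia and glycolysis, the unfolded protein response, p53 targets, apoptosis, receptor kinases, MAPK output, Wnt, Notch and Hippo targets, ribosome biogenesis with MYC targets, stem cell markers, autophagy and lysosome, other cell types, mitochondrially encoded genes and housekeeping genes. The mitochondrial list had 0 members in the table, so 31 were tested with limma's camera (preset correlation 0.01), adjusted over the lists of a contrast. Each was also tested with the correlation estimated from the residuals, and with fry, which tests whether genes of a list move on balance one way without comparing them with other genes.

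Named genes are the 12 largest rises and 12 largest falls per line, 6 each way for the difference and for the untreated lines, and 6 each way for the shared response, ranked by the smaller change. They had an adjusted p below 0.05, a mean of at least 2 FPKM in the higher group, and both libraries of 1 group beyond both of the other. Members of a fixed list could be named with the list, and genes nearest to the 10 highest super-enhancers with those.

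Coordinates are GRCh38 throughout. The gene table (GRCh38.p14, 38340 genes) has no strand, so transcription start sites could not be placed. A gene end, meaning the region within 2 kb of either annotated end, took their place, and chromosome lengths were taken as the largest coordinate seen (3086.58 Mb in all). Peaks overlapped if they shared at least 1 bp (bedtools 2.31.1). Overlaps were set against 100 shuffles of the peaks over the genome, and co-occupancy also against shuffles within the union of the H3K4me1 list and those labelled H3K27ac and RNAPol2. Super-enhancers were called from the list labelled H3K27ac. Peaks within 2.5 kb of a gene end were left out, the others were stitched over gaps of up to 12.5 kb, and stitched regions were ranked by the sum of fold enrichment times width and split at the point where the slope of the ranked curve reaches 1. Genes were compared between bound sets with camera, Fisher's exact test and 10000 random lists matched for mean expression. A gene was restricted to a line if the untreated lines differed in it at an adjusted p below 0.05, with a mean of at least 5 FPKM in 1 line and less than 0.5 in the other, and silent if it had less than 0.05 in both. Other tools were python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives covered the pseudocount, filter, scaling, trend, fold minimum, pairing by title tag, each line's own libraries, leaving out each library, the correlation within lists, peak thresholds, overlap definitions and stitching.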

Results

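RNA of MCF-7 and MDA-MB-231 breast cancer cells was measured with DMSO and after 4 weeks of JQ1, with 2 libraries in each of the 4 groups. Peaks of BRD4, of the histone demethylase LSD1, of MTA3, a subunit of the NuRD repressor complex, and of H3K4me1, a mark of enhancers, were listed for MCF-7 with 1 library each. So were peaks of libraries labelled H3K27ac, a mark of active enhancers and promoters, and RNAPol2, RNA polymerase II. Between 15923 and 16603 of 18710 genes were above 0 FPKM per library, and the 10 highest genes took 5.51% to 12.3% of the total. Levels are mean FPKM ± SD (n = 2 libraries), and changes are log2 of FPKM plus 1. For genes named by rank, both libraries of 1 group lay beyond both of the other. The depth of the RNA libraries is unknown, since FPKM hold no counts.

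The first comparison asks which genes JQ1 changed in MCF-7. Genes of the oestrogen receptor programme were among those that fell furthest. GREB1 (gene ID 9687, chromosome 2, 11482888 to 11642788), an oestrogen-induced cofactor of the receptor, fell from 126 ± 70.8 to 3.54 ± 1.22 FPKM (-4.71, SE 0.37, adjusted p 0.0003623). IGFBP5, a binding protein of insulin-like growth factors, fell from 44.9 ± 19.1 to 1.04 ± 0.156, and CALML5, a calmodulin-like protein, from 46.8 ± 21.7 to 1.08 ± 0.325. AGR3, a secretory pathway protein of luminal cells, fell from 17.8 ± 3.51 to 0.220 ± 0.0707. GFRA1, a receptor of glial cell line-derived factors, fell from 62.6 ± 16.7 to 4.32 ± 1.76. The receptor itself, ESR1, a luminal marker, went from 44.2 ± 3.13 to 8.14 ± 0.339 (-2.31, adjusted p 0.0009931). Of 26 genes of the oestrogen response list, 14 fell and 0 rose (20 fell when adjusted over the list alone, median -1.26, camera adjusted p 4.261e-08, adjusted p = 0.4444 with an estimated correlation). They included CXCL12 (21.4 ± 1.80 to 1.04 ± 0.474), IGFBP4 (138 ± 17.3 to 22.5 ± 8.27) and PGR, the progesterone receptor (6.43 ± 3.39 to 0.45 ± 0.24). Luminal markers were split, with 1 up and 6 down of 24 (2 and 6 when adjusted over the list alone, camera adjusted p 0.4807). GATA3, a luminal transcription factor, rose from 454 ± 2.31 to 752 ± 50.9, while XBP1 fell from 856 ± 142 to 115 ± 39.7.

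Genes of DNA replication, interferon response and MYC-type oncogenes also fell in MCF-7. Of 28 replication genes, 23 fell and 0 rose (25 adjusted over the list alone, median -1.50, camera adjusted p 6.383e-12, adjusted p = 0.7086 with an estimated correlation). MCM5 (4174, chromosome 22, 35400140 to 35455031), a subunit of the replicative helicase, fell from 35.4 ± 2.57 to 3.31 ± 0.806. Of 28 mitosis genes, 10 fell and 18 did not pass (15 fell when adjusted over the list alone, median -0.59, camera adjusted p 0.0004173, adjusted p = 0.8429 with an estimated correlation). Of 33 interferon-stimulated genes, 18 fell and 1 rose (23 and 2 adjusted over the list alone, median -1.12, camera adjusted p 1.717e-06, adjusted p = 0.8185 with an estimated correlation). OAS1, a sensor of viral RNA, fell from 36.7 ± 10.7 to 2.02 ± 0.679 FPKM, OAS3 from 30.5 ± 9.33 to 2.16 ± 0.269 and PARP9 from 21.5 ± 7.65 to 1.55 ± 0.0849, while IRF7 rose from 11.3 ± 1.99 to 22.8 ± 6.36. Of 11 BET-dependent oncogenes, 7 fell (7 adjusted over the list alone, median -1.20, camera adjusted p 0.0003781, adjusted p = 0.3738 with an estimated correlation), among them MYC (28 ± 2.55 to 5.89 ± 0.841), CCND1, cyclin D1 (166 ± 5.79 to 40.4 ± 2.41), and MYB (11.1 ± 3.33 to 0.990 ± 0.453). Of 24 genes of ribosome biogenesis and MYC targets, 10 fell (11 adjusted over the list alone, median -0.62, camera adjusted p 0.001714, adjusted p = 0.8429 with an estimated correlation), with RRS1 going from 34.4 ± 11.4 to 7 ± 1.59. Of 28 NF-kB and inflammatory genes, 5 fell (5 adjusted over the list alone, median -0.68, camera adjusted p 0.03541, adjusted p = 0.8429 with an estimated correlation), among them TNFAIP2 and BCL3. The NF-kB call ended without MCF-7 DMSO replicate 1 (adjusted p 0.5406) and without MCF-7 JQ1 replicate 2 (0.111), and its adjusted p ranged from 1.529e-05 to 0.5406 over the alternatives.

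Histone genes, HEXIM1 and lysosomal genes rose in MCF-7. HEXIM1, an inhibitor of the elongation factor P-TEFb, rose from 14.5 ± 0.820 to 94.5 ± 39.5 FPKM (2.56, adjusted p 0.0006922), and H1-2 (3006, chromosome 6, 26055740 to 26056470), a linker histone, from 42.3 ± 1.82 to 354 ± 36.1 (3.03, SE 0.30, adjusted p 0.0006833). Of the 11 genes listed with HEXIM1 and polyadenylated histones, 8 rose and 0 fell (9 adjusted over the list alone, median 2.32, camera adjusted p 1.717e-06, adjusted p = 0.3738 with an estimated correlation). Core histones outside that list rose as well, with H2BC8 at 8.99 ± 1.41 without and 128 ± 7.25 with JQ1, H3C10 at 15.8 ± 1.14 and 149.6 ± 5.24, and H2AC8 at 14.6 ± 0.537 and 134 ± 51.5. SERPINI1 (5274, chromosome 3, 167735721 to 167825569), neuroserpin, which belongs to the same list, rose from 0.245 ± 0.0495 to 20.6 ± 13.3. Of 19 autophagy and lysosome genes, 9 rose and 1, TFEB, fell (9 and 1 adjusted over the list alone, median 0.58, camera adjusted p 0.001714, adjusted p = 0.8185 with an estimated correlation). MAP1LC3B, which coats autophagosomes, rose from 66.9 ± 11.5 to 198 ± 58.1. ARC and S100A9 are among the genes named by rank, but their calls ended when single libraries were left out and when MCF-7 was fitted by itself (0.05884 and 0.07418). ARC rose by 3.23 (adjusted p 0.01603, and 0.07828 and 0.0726 without MCF-7 DMSO replicate 1 and 2, in a range of 0.003425 to 0.07828), and S100A9 fell by 3.64 on the log2 scale (adjusted p 0.01875, and 0.1036 and 0.1266 without MCF-7 DMSO replicate 2 and JQ1 replicate 1, in a range of 9.709e-05 to 0.1266). HBA1, alpha globin, from the list of other cell types, rose from 2.65 ± 0.113 to 20.6 ± 15.1, and ACTA2, smooth muscle actin, fell from 3.41 ± 1.34 to 0.940 ± 0.0566. They were the 1 rise and 1 fall among 9 such genes (1 and 1 adjusted over the list alone, camera adjusted p 0.7674).

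Other lists were not called in MCF-7, with camera adjusted p from 0.06971 to 0.9864. Of 13 ABC transporters of drug efflux, 4 rose and 3 fell (4 and 3 adjusted over the list alone): ABCC10 (10.1 ± 2.16 to 33.1 ± 7.15), ABCG1, ABCC5 and ABCA3 up, and ABCC4 (4.79 ± 0.332 to 1.09 ± 0.191) and ABCC3 (12.3 ± 7.78 to 2.4 ± 1.03) down among others. Of 19 drug metabolism enzymes, 1 rose and 7 fell (2 and 7 over the list alone), with UGT1A6, which conjugates drugs to glucuronic acid, falling from 32.2 ± 8.13 to 2.23 ± 2.35. Of 17 BET proteins and elongation factors, 2 rose and 3 fell (2 and 3 over the list alone). BRD2 rose from 93.2 ± 2.06 to 274 ± 29.4, MED12 fell from 10.5 ± 0.502 to 3.34 ± 0.0990, and BRD4 was at 30.3 ± 4.24 and 38.2 ± 2.06 (adjusted p 0.1711). In the LSD1, CoREST and NuRD list 6 of 18 fell and 1 rose (7 and 1 over the list alone, camera adjusted p 0.08063). MTA3 fell from 23.4 ± 4.94 to 6.87 ± 2.31, and CHD3, the NuRD remodeller, from 35.9 ± 0.198 to 13.2 ± 0.516, while KDM1A, the gene of LSD1, was at 56.7 ± 1.15 and 50.2 ± 1.61 (adjusted p 0.4305). Of 7 genes the study itself deals with, a list that is not independent evidence, PELI1, a ubiquitin ligase, and PDPK1, a kinase upstream of AKT, rose (3.69 ± 0.148 to 7.64 ± 0.417, and 14.0 ± 0.516 to 25.8 ± 4.65), MYC and MTA3 fell, and GNA13, a G protein subunit, did not pass (2 and 2 over the list alone).

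Members rose and fell as follows in the remaining MCF-7 lists, with the counts adjusted over the list alone in parentheses. Counts were 2 and 4 of 24 mesenchymal markers (2 and 4), 1 and 0 of 11 basal markers (0 and 0), 2 and 3 of 16 antigen presentation genes (2 and 4), 1 and 3 of 25 cholesterol genes (1 and 2), and 3 and 6 of 19 lipid storage genes (4 and 6). They were 2 and 0 of 22 hypoxia genes (0 and 0), 2 and 1 of 22 genes of the unfolded protein response (1 and 1), 5 and 1 of 20 p53 targets (5 and 1), 1 and 2 of 23 apoptosis genes (1 and 2), and 4 and 5 of 24 receptor kinase genes (5 and 5). They were 3 and 3 of 22 MAPK genes (3 and 3), 4 and 2 of 22 Wnt genes (4 and 4), 4 and 3 of 19 Notch and Hippo genes (4 and 3), 1 and 2 of 11 stem cell markers (1 and 2), and 1 and 1 of 14 housekeeping genes (1 and 1). PPARG, a regulator of fat storage, fell from 30.7 ± 10.2 to 3.81 ± 1.53, and DGAT1, which makes triglycerides, rose from 13.2 ± 2.26 to 75.8 ± 45.3. Median, mean and test differed in sign for the lists of BET proteins, ABC transporters, cholesterol, unfolded protein response, MAPK, Wnt and stem cell genes. In all, 1596 genes rose and 2304 fell of 13219 tested in MCF-7 (29.5%), and 684 and 1285 of these by at least 2-fold. That total of 3900 was 1753, 1725, 1363 and 2454 without DMSO replicates 1 and 2 and JQ1 replicates 1 and 2. The share that rose was 40.9% with FPKM as deposited and 51.6% after quantile normalization. With an estimated correlation none of the 31 lists was called by camera (3 at an unadjusted p below 0.05), and fry called 9.

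**Figure D1:**
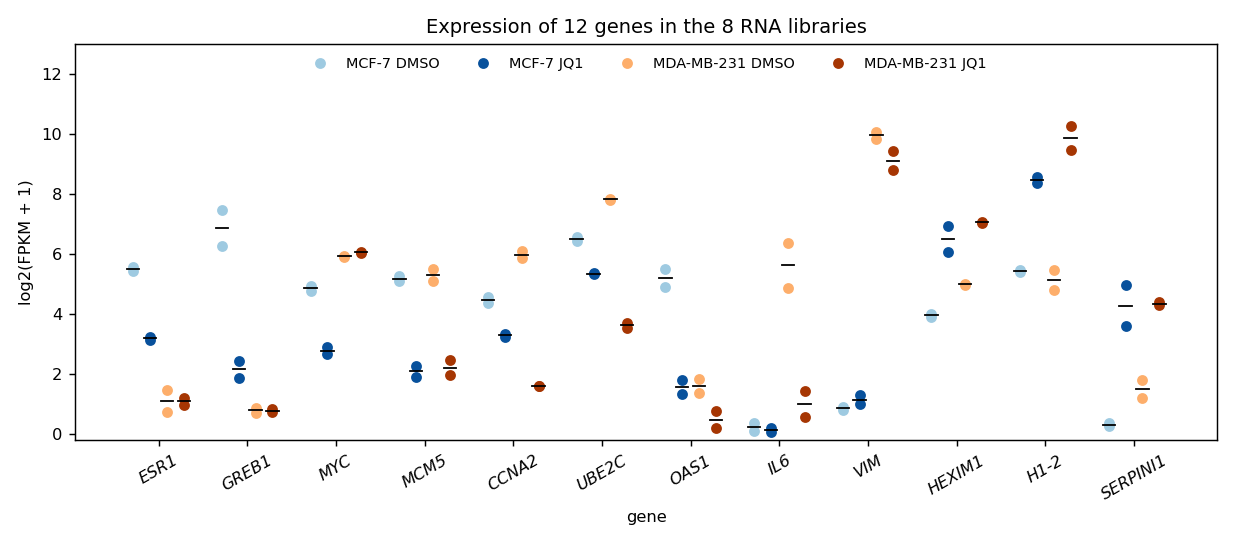
Expression of 12 genes, each point 1 RNA library and each black line the mean of 2 libraries, on a vertical axis of log2(FPKM + 1), for MCF-7 and MDA-MB-231 without (DMSO) and with JQ1. MYC fell in MCF-7 (28 to 5.89 FPKM) and was at 59.8 and 66.1 in MDA-MB-231, while MCM5 fell and HEXIM1 rose in both lines.

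The second comparison asks the same of MDA-MB-231, where genes of cell division fell furthest along with cytokines. CCNA2 (890, chromosome 4, 121816444 to 121823883), cyclin A2, fell from 62.6 ± 8.29 to 2.05 ± 0.0141 FPKM (-4.38, SE 0.17, adjusted p 2.654e-05), and UBE2C (11065, chromosome 20, 45812644 to 45816952), which marks mitotic cyclins for destruction, from 226 ± 2.25 to 11.3 ± 0.948 (-4.20, adjusted p 2.047e-05). All 28 mitosis genes fell (28 adjusted over the list alone, median -3.12, camera adjusted p 2.768e-24, adjusted p = 0.3067 with an estimated correlation). MKI67, a marker of dividing cells, fell from 64.3 ± 12.3 to 4.22 ± 0.573, and TOP2A from 123 ± 39.8 to 7.57 ± 0.771. All 28 replication genes fell as well (28 adjusted over the list alone, median -2.36, camera adjusted p 2.593e-19, adjusted p = 0.3067 with an estimated correlation), with TYMS, thymidylate synthase, at 177 ± 70.9 without and 14.4 ± 5.02 with JQ1. CSF2 (1437, chromosome 5, 132073789 to 132076170), the growth factor GM-CSF, fell from 43.8 ± 20.6 to 0.575 ± 0.318 (-4.76, SE 0.31, adjusted p 9.578e-05), and IL6 (3569, chromosome 7, 22727200 to 22731998), an inflammatory cytokine, from 55.0 ± 37.8 to 1.11 ± 0.884. Of 28 NF-kB and inflammatory genes, 13 fell and 0 rose (16 adjusted over the list alone, median -1.14, camera adjusted p 0.001383, adjusted p = 0.7147 with an estimated correlation), among them CXCL1 (70.2 ± 27.8 to 6.68 ± 0.453) and IL1B (12.9 ± 10.8 to 0.150 ± 0.0990).

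Members of the mesenchymal, interferon and BET-dependent lists fell in MDA-MB-231, while MYC did not pass. Of 24 mesenchymal markers, 12 fell and 1 rose (12 and 1 adjusted over the list alone, median -0.77, camera adjusted p 0.002541, adjusted p = 0.28 with an estimated correlation). CAV1, caveolin, fell from 159 ± 23.3 to 43.3 ± 11.3, MMP14, a membrane-bound collagenase, from 197 ± 90.7 to 57.8 ± 17.1 and VIM, vimentin, from 993 ± 111 to 566 ± 175, while TGFB1 rose from 52.3 ± 15.5 to 124 ± 3.65. Of 33 interferon-stimulated genes, 14 fell and 2 rose (16 and 2 adjusted over the list alone, median -1.03, camera adjusted p 0.007995, adjusted p = 0.7147 with an estimated correlation), with IFIT3 going from 69.4 ± 2.10 to 11.4 ± 1.68 and IRF7 from 7.61 ± 1.92 up to 70.2 ± 0.651. Of 11 BET-dependent oncogenes, 7 fell (8 adjusted over the list alone, median -1.22, camera adjusted p 0.0033, adjusted p = 0.3067 with an estimated correlation), among them FOSL1 (284 ± 12.1 to 122 ± 3.58) and FOXM1 (77.7 ± 9.04 to 16.1 ± 1.37). MYC was at 59.8 ± 0.764 without and 66.1 ± 1.22 with JQ1 (0.14, adjusted p 0.5416). Of 24 ribosome and MYC target genes, 7 fell (11 adjusted over the list alone, median -0.55, camera adjusted p 0.01312, adjusted p = 0.7216 with an estimated correlation). That call ended without MDA-MB-231 DMSO replicate 2 (adjusted p 0.3302) and without JQ1 replicate 2 (0.05895), in a range from 5.286e-05 to 0.3302 over the alternatives.

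Some histone and lysosomal genes, PEG10 and MT1A rose in MDA-MB-231. Of all 60 histone genes tested, 27 rose and 1, H4C12, fell, while in MCF-7 53 rose and 0 fell. H1-2 rose from 34.8 ± 11.6 to 974 ± 372 FPKM (4.75, SE 0.30, adjusted p 9.578e-05), H2BC5 from 15.0 ± 8.59 to 434 ± 147, and the copies H2AC18 and H2AC19, which carry identical values, from 7.73 ± 5.46 to 424 ± 241. Of the 11 genes listed with HEXIM1 and polyadenylated histones, 10 rose and 0 fell (10 adjusted over the list alone, median 3.78, camera adjusted p 7.932e-10, adjusted p = 0.28 with an estimated correlation), and HEXIM1 rose from 30.7 ± 0.311 to 132 ± 3.46. PEG10 (23089, chromosome 7, 94656325 to 94669695), an imprinted gene derived from a retrotransposon, rose from 18.9 ± 12.9 to 449 ± 60.2 (4.66, SE 0.40, adjusted p 0.0002616). MT1A, a metallothionein, rose from 3.31 ± 1.37 to 79.7 ± 38.0, and CCN2, connective tissue growth factor, from 82.8 ± 46.6 to 1134 ± 312. Of 19 autophagy and lysosome genes, 9 rose and 0 fell (9 adjusted over the list alone, median 0.62, camera adjusted p 0.0003488, adjusted p = 0.5974 with an estimated correlation), among them SQSTM1, the autophagy receptor p62 (369.9 ± 198 to 1950 ± 704), and the sialidase NEU1 (64.6 ± 49.5 to 322 ± 216). Among 9 genes of other cell types, HBA1 rose (0.410 ± 0.0566 to 3.83 ± 1.05), and ACTA2 (1.76 ± 0.184 to 0.620 ± 0.141) and PECAM1, an endothelial marker, fell (1 and 2 adjusted over the list alone, camera adjusted p 0.9382). The solute carrier SLCO4A1 is among the genes named by rank at 22.4 ± 21.3 and 0.170 ± 0.0141 (adjusted p 0.003018), but not past the threshold when MDA-MB-231 was fitted by itself (0.05323, the highest of a range from 0.0004958).

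The remaining lists were not called in MDA-MB-231 (camera adjusted p 0.05914 to 0.9382). Members rose and fell, with counts adjusted over the list alone in parentheses, as follows. They were 2 and 3 of 17 BET proteins and elongation factors (2 and 4), 1 and 7 of 18 genes of LSD1, CoREST and NuRD (1 and 7), 0 and 1 of 7 genes of the study's topic (0 and 1), 3 and 1 of 13 ABC transporters (3 and 1), and 2 and 2 of 19 drug metabolism genes (2 and 2). They were 2 and 5 of 26 oestrogen response genes (2 and 5), 2 and 6 of 24 luminal markers (3 and 6), 0 and 5 of 11 basal markers (0 and 5), 0 and 5 of 16 antigen presentation genes (0 and 5), 3 and 3 of 25 cholesterol genes (2 and 1), and 2 and 2 of 19 lipid storage genes (2 and 2). They were 1 and 1 of 22 hypoxia genes (1 and 1), 5 and 2 of 22 genes of the unfolded protein response (5 and 2), 6 and 3 of 20 p53 targets (6 and 3), 2 and 5 of 23 apoptosis genes (2 and 10), and 5 and 8 of 24 receptor kinase genes (6 and 9). They were 4 and 8 of 22 MAPK genes (4 and 8), 1 and 7 of 22 Wnt genes (1 and 7), 3 and 4 of 19 Notch and Hippo genes (3 and 4), 0 and 3 of 11 stem cell markers (0 and 3), and 0 and 1 of 14 housekeeping genes (0 and 0). BRD2 rose from 93.7 ± 0.707 to 454 ± 109 FPKM, MTA3 fell from 9.81 ± 2.13 to 3.50 ± 2.18, ABCC10 rose from 8.46 ± 3.15 to 36.5 ± 4.75 and VEGFA, an angiogenic factor, fell from 133 ± 117 to 15.2 ± 9.09. Median, mean and test differed in sign for the lists of BET proteins, the study's topic, drug metabolism, lipid storage, hypoxia, receptor kinases and housekeeping. In all, 1359 genes rose and 2348 fell (28%), with 619 and 1307 of these changed at least 2-fold. That total of 3707 was 2070 without JQ1 replicate 1 and 1127 with MDA-MB-231 fitted by itself. The share that rose was 36.7% as deposited and 52.5% after quantile normalization, which moved the median change of all genes from -0.0767 to 0.0311. With an estimated correlation none of the 31 lists was called by camera (5 at an unadjusted p below 0.05), and fry called 9.

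**Figure D2:**
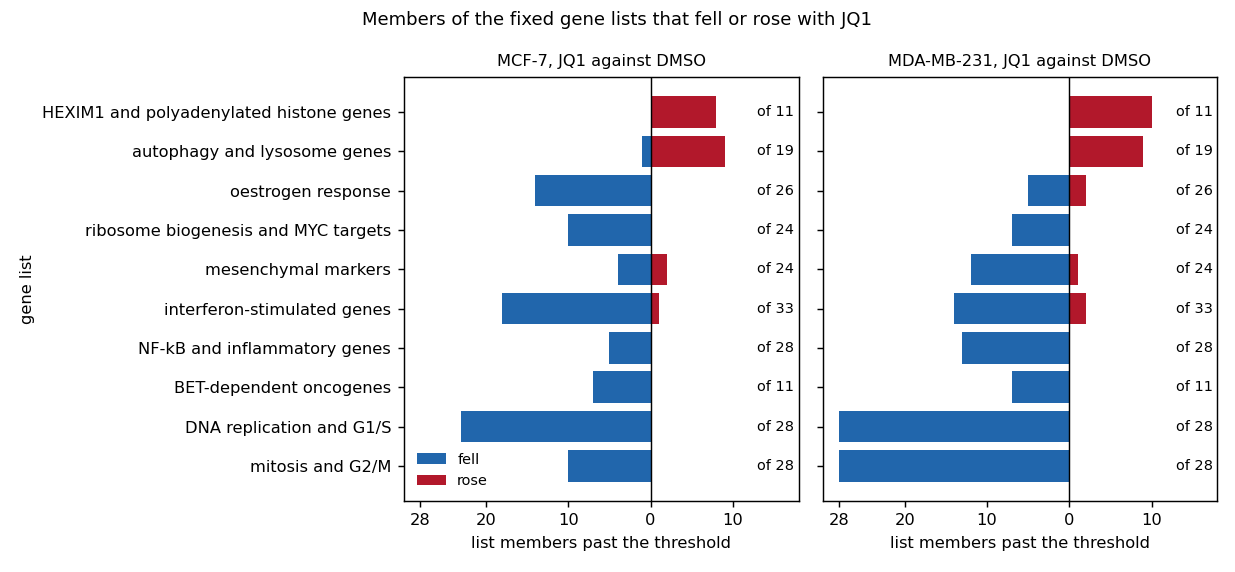
Number of genes that fell (bars to the left) and rose (bars to the right) with JQ1 in the 10 gene lists called in either line, with the number tested at the right, for MCF-7 and MDA-MB-231. Of 28 mitosis genes 10 fell in MCF-7 and 28 in MDA-MB-231, and of 26 oestrogen response genes 14 and 5 fell.

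The third comparison tests where the JQ1 effect differed between the lines. Most mitosis genes fell further in MDA-MB-231. Genes of the oestrogen response fell in MCF-7, while 22 of 26 were already lower in untreated MDA-MB-231, which leaves them less room to fall there (GREB1 0.730 ± 0.127 and 0.710 ± 0.0849 FPKM). CDC20, the activator of the anaphase-promoting complex, was at 53.1 ± 0.933 and 60.0 ± 1.58 FPKM in MCF-7 and fell from 148 ± 9.57 to 14.4 ± 0.679 in MDA-MB-231 (difference -3.45, SE 0.19, adjusted p 0.0009061). Of 28 mitosis genes, 26 were lower in the difference and 2 did not pass (27 lower when adjusted over the list alone, median -2.57, camera adjusted p 6.512e-33, adjusted p = 0.3242 with an estimated correlation). CDCA8, a chromosomal passenger protein, went from 17.9 ± 0.148 to 12.2 ± 0.0495 in MCF-7 and from 52.7 ± 2.38 to 2.61 ± 0.0283 in MDA-MB-231 (-3.38). Of 26 oestrogen response genes, 8 were higher in the difference and 18 did not pass (14 higher when adjusted over the list alone, median 0.96, camera adjusted p 1.828e-11, adjusted p = 0.3242 with an estimated correlation). MYC was higher as well (2.22, adjusted p 0.002824). Of the 28 replication genes 1 was lower (13 adjusted over the list alone, median -0.83, camera adjusted p 1.835e-08, adjusted p = 0.5912 with an estimated correlation).

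Genes with opposite or 1-sided responses included PEG10 (difference 4.22, SE 0.56, adjusted p 0.007692) and ADGRF1, an adhesion G protein-coupled receptor, at 0.280 ± 0.0707 and 0.440 ± 0.0566 FPKM in MCF-7, falling from 19.6 ± 1.55 to 0.440 ± 0.0141 in MDA-MB-231 (-4.01, SE 0.23). AQP3, a water and glycerol channel, fell in MCF-7 from 63.2 ± 10.4 to 25.8 ± 15.3 and rose in MDA-MB-231 from 5.50 ± 1.79 to 25.1 ± 8.95 (3.37, adjusted p 0.02138). CALCR, the calcitonin receptor, went from 11.1 ± 1.25 to 1.2 ± 0.354 and from 0.205 ± 0.177 to 1.12 ± 0.198 (3.29), and NGFR, a neurotrophin receptor, rose in MCF-7 from 0.285 ± 0.106 to 9.90 ± 4.66 (-4.12). The calls of AQP3, DHRS2, NGFR, CSF3 and H4C12 ended without single libraries, while the lowest adjusted p over their alternatives were 0.001573, 0.001277, 0.001433, 0.008913 and 0.004765. The adjusted p were 0.05076 to 0.0797 for AQP3, over 5 of the 8 libraries (MCF-7 DMSO replicates 1 and 2 and JQ1 replicate 2, MDA-MB-231 DMSO replicate 2 and JQ1 replicate 1). For DHRS2 they were 0.07291 and 0.05712 without MCF-7 JQ1 replicates 1 and 2, and for H4C12 0.05446 and 0.05105 without MDA-MB-231 JQ1 replicates 1 and 2. For NGFR they were 0.05466, 0.0696 and 0.05334 without MCF-7 DMSO replicate 1, MCF-7 JQ1 replicate 1 and MDA-MB-231 JQ1 replicate 2. For CSF3 they were 0.06514 to 0.1553 without any single one of the 4 MCF-7 and 2 MDA-MB-231 JQ1 libraries. The call of CSF3 also ended with 0.1 added in place of 1 (0.06797) and with no filter (0.0941), and that of AQP3 with no filter (0.05366). MT1A (3.90, adjusted p 0.007188) was not past the threshold with 0.1 added in place of 1 (0.1303, the highest of a range from 0.000955).

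Of the other lists, 3 of 11 genes listed with HEXIM1 and histones were higher in the difference (6 adjusted over the list alone, median 1.5, camera adjusted p 0.006226, adjusted p = 0.4557 with an estimated correlation). Of 24 mesenchymal markers, 2 were lower and 1, TGFB1, was higher (9 and 1 adjusted over the list alone, median -0.67, camera adjusted p 0.006226, adjusted p = 0.3242 with an estimated correlation). Of 33 interferon genes, 5 were higher and 2 lower (12 and 7 adjusted over the list alone, median 0.67, camera adjusted p 0.03244, adjusted p = 0.8682 with an estimated correlation). The mesenchymal call ended without MDA-MB-231 DMSO replicate 1 (0.06027) and with 0.1 added in place of 1 (0.07084), in a range from 0.001958. The interferon call ended without that library too (0.06027), and without MCF-7 DMSO replicate 2 (0.3465) or MDA-MB-231 JQ1 replicate 2 (0.1004), in a range from 3.186e-05. The other 25 lists were not called, and 3 of 19 drug metabolism genes, UGT1A6, AKR1C1 and AKR1C2, were higher (4 and 1 lower adjusted over the list alone), having fallen in MCF-7 alone. UGT1A6 was at 0 FPKM in MDA-MB-231 without and with JQ1, so it could not fall there. Median, mean and test differed in sign for the lists of BET-dependent oncogenes, BET proteins, the study's topic, MAPK, and Notch and Hippo. In all, 262 genes were higher and 328 lower in MDA-MB-231 (590, 4.46%), or 161 and 218 with 0.1 added in place of 1. With libraries paired by title tag, a pairing that no label states, 674 were higher and 801 lower. The higher and lower counts were 189 and 129 without MCF-7 DMSO replicate 1 and 165 and 142 without its replicate 2, which turns the majority, and 83 and 96, and 98 and 130, without MCF-7 JQ1 replicates 1 and 2. They were 110 and 121, and 106 and 193, without MDA-MB-231 JQ1 replicates 1 and 2, and 154 and 328 without MDA-MB-231 DMSO replicate 2. With an estimated correlation camera called none of the 31 lists (3 at an unadjusted p below 0.05), and fry called 3.

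The fourth comparison sets the untreated lines, and with them their media, side by side. VIM (7431, chromosome 10, 17228241 to 17237593) was at 0.810 ± 0.0849 FPKM in MCF-7 and 993 ± 111 in MDA-MB-231 (9.10, SE 0.23, adjusted p 2.908e-07). TFF1 (7031, chromosome 21, 42362282 to 42366535), an oestrogen-induced secreted peptide, was at 3765 ± 2344 and 3.44 ± 1.25 (-9.60, SE 0.41, adjusted p 2.087e-06). AXL, a receptor kinase of mesenchymal tumours, was at 0.515 ± 0.0212 and 269.6 ± 25.1, moesin (MSN), a cytoskeletal linker, at 0.150 ± 0.0141 and 277 ± 16.7, and the glutathione peroxidase GPX1 at 0.195 ± 0.00707 and 271 ± 48.6. SPTSSB, a subunit of sphingolipid synthesis, was at 572 ± 37.8 and 0.180 ± 0.0849, and FXYD3, an ion pump regulator, at 366 ± 25.5 and 0.2 ± 0.283. Of 24 luminal markers, 23 were lower and 0 higher in MDA-MB-231 (23 adjusted over the list alone, median -4.42, camera adjusted p 2.025e-13, adjusted p = 0.08418 with an estimated correlation), among them CDH1, E-cadherin (142 ± 12.9 and 0.395 ± 0.134), and ESR1 (44.2 ± 3.13 and 1.21 ± 0.771). Of 24 mesenchymal markers, 21 were higher and 0 lower (21 adjusted over the list alone, median 2.87, camera adjusted p 5.36e-12). This is the 1 list that held with an estimated correlation (adjusted p = 0.0396 with an estimated correlation).

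Of 26 oestrogen response genes, 22 were lower and 2 higher in MDA-MB-231 (22 and 2 adjusted over the list alone, median -2.60, camera adjusted p 3.327e-08, adjusted p = 0.3376 with an estimated correlation). Of 16 antigen presentation genes, 14 were higher (14 over the list alone, median 1.55, camera adjusted p 2.778e-06, adjusted p = 0.5836 with an estimated correlation), with HLA-A at 152 ± 21.1 and 1029 ± 527 FPKM and CD74 at 1.01 ± 0.856 and 283 ± 165. Of 28 mitosis genes, 24 were higher and 1 lower (24 and 1 over the list alone, median 1.24, camera adjusted p 1.393e-07, adjusted p = 0.6172 with an estimated correlation). MAPK output genes were higher for 15 of 22 and lower for 1 (15 and 2 over the list alone, median 1.46, camera adjusted p 0.0004064, adjusted p = 0.3376 with an estimated correlation). For NF-kB genes 13 of 28 were higher and 3 lower (13 and 3 over the list alone, median 0.99, camera adjusted p 0.01475, adjusted p = 0.7171 with an estimated correlation). For BET-dependent oncogenes 7 of 11 were higher and 1 lower (7 and 1 over the list alone, median 1.07, camera adjusted p 0.0428, adjusted p = 0.4884 with an estimated correlation). Of 24 ribosome and MYC target genes 6 were higher and 0 lower (6 over the list alone, median 0.42, camera adjusted p 0.03264, adjusted p = 0.7697 with an estimated correlation). Of 20 p53 targets 3 were higher and 10 lower (3 and 11 over the list alone, median -0.87, camera adjusted p 0.03264, adjusted p = 0.6172 with an estimated correlation). Without MDA-MB-231 DMSO replicate 2 the calls of the BET-dependent (0.0556), p53 (0.05101) and ribosome (0.3528) lists ended. The p53 call also ended without MCF-7 DMSO replicate 1 (0.08143), and those of NF-kB and ribosome genes without MCF-7 DMSO replicate 2 (both 0.1316). The lowest adjusted p over the alternatives were 0.03929, 0.01122, 0.0002765 and 0.0001069 for the BET-dependent, p53, ribosome and NF-kB lists. In all, 3172 genes were higher and 3532 lower in MDA-MB-231 (6704, 50.7%), 1954 and 2131 of them at least 2-fold. The other 21 lists were not called, and median, mean and test differed in sign for those of the unfolded protein response, receptor kinases and autophagy.

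The fifth comparison asks how far the 2 lines shared their response. A core of replication genes fell in both. MCM5 fell from 38.9 ± 7.56 to 3.71 ± 1.10 FPKM in MDA-MB-231, by 3.09 on the log2 scale, as in MCF-7. CDC45, a component of the active replicative helicase, fell from 20.3 ± 1.62 to 1.95 ± 0.594 in MCF-7 and from 22.6 ± 7.06 to 1.89 ± 0.219 in MDA-MB-231. UHRF1, which maintains DNA methylation, fell from 21.4 ± 2.26 to 1.48 ± 0.283 and from 46.4 ± 12.9 to 2.17 ± 0.629. SPDEF, an epithelial transcription factor, fell from 20.6 ± 2.22 to 0.785 ± 0.205 and from 19.2 ± 16 to 0.385 ± 0.177, and KYNU, an enzyme of tryptophan breakdown, from 114 ± 41.5 to 6.39 ± 3.48 and from 21.4 ± 2.78 to 1.96 ± 0.884. DCXR (51181, chromosome 17, 82035858 to 82037697), a xylulose reductase, rose from 85.8 ± 8.37 to 581 ± 104 in MCF-7 and from 40.0 ± 4.93 to 292 ± 30 in MDA-MB-231 (2.74 and 2.84, adjusted p 0.0003314 and 9.578e-05). H1-2 and SERPINI1 rose in both as well. Among the genes named above, UHRF1 overlaps ARRDC5, CCNA2 overlaps EXOSC9 and H2AC19 overlaps H4C15, which leaves their levels uncertain.

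In all, 756 genes rose in both lines, where 164 would be shared by chance (odds ratio 16.4, 95% interval 14.4 to 18.7), and 1167 fell in both, against 409 (odds ratio 8.46, 7.63 to 9.37). After quantile normalization 1122 rose and 892 fell in both, so that the share that rose went from 39.3% to 55.7%. Both p were too small to be given by Fisher's exact test. Opposite calls were made for 17 genes up in MCF-7 and down in MDA-MB-231 (283 by chance, Fisher's exact p 3.787e-116) and for 12 the other way (237 by chance, p 7.313e-99). GATA3 is among the former, at 5.01 ± 0.382 and 1.29 ± 0.403 FPKM in MDA-MB-231. ITGA6, an integrin of basal cells, is another, at 1.77 ± 0.0919 and 6.71 ± 3.67 in MCF-7 and 76.2 ± 31.7 and 22.8 ± 7.41 in MDA-MB-231. Across the 13219 genes, which are not independent replicates, the 2 effects had a Pearson r of 0.594 and a Spearman rho of 0.641. Of the 5655 genes called in either line, 86.1% had the same sign in both. The 1923 shared genes numbered 723 and 875 without MCF-7 JQ1 replicate 1 and DMSO replicate 1, 875 without DMSO replicate 2, 1230 without JQ1 replicate 2, and 1202 without MDA-MB-231 JQ1 replicate 1.

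The ChIP-seq lists address where BRD4, LSD1 and MTA3 bind in MCF-7 and how far they share sites. BRD4 had 43300 peaks over 46.0 Mb (1.49% of the genome, median width 684 bp), LSD1 65574 over 52.0 Mb and MTA3 40264 over 27.9 Mb. H3K4me1 had 149985 peaks over 193 Mb, and the lists labelled H3K27ac and RNAPol2 had 94841 over 138 Mb and 77051 over 169.5 Mb, after 66 and 50 peaks on other contigs were left out. With 1 library per antibody, these numbers have no replicate error, and the intervals below cover counting only. Gene ends held 40.6% of BRD4, 30.9% of LSD1 and 41.7% of MTA3 peaks, against 8.22% of the genome. Of BRD4 peaks, 71.5% overlapped an LSD1 peak (95% exact binomial interval 71.1 to 71.9%, 4.18% in shuffles), 57.1% an MTA3 peak (56.6 to 57.5%, 2.47%) and 83.9% an H3K4me1 peak (83.6 to 84.3%, 11.6%). The overlap with the list labelled H3K27ac was 56.9% (56.4 to 57.4%, 7.99%) and with that labelled RNAPol2 43.7% (43.2 to 44.2%, 8.99%). MTA3 peaks overlapped LSD1 in 82.4% and BRD4 in 71.8%. Among the 10000 strongest peaks of each list, BRD4 overlapped LSD1 in 28.94% and MTA3 overlapped LSD1 in 43.75%.

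Of BRD4 peaks, 22762 or 52.6% (95% exact binomial interval 52.1 to 53%) overlapped both an LSD1 and an MTA3 peak by at least 1 bp. These are called co-occupied sites, although LSD1 and MTA3 need not overlap each other there. With summits within 250 bp the share was 25.04%. Shuffles gave 0.426% over the genome and 13% within regulatory regions (384.6 Mb), a ratio of 4.03 to the latter. Those regions include the lists labelled H3K27ac and RNAPol2, which did not favour MCF-7 genes (below). Within H3K4me1 peaks alone, a choice made after the data were seen, shuffles gave 16.9%, a ratio of 3.10. If LSD1 and MTA3 overlapped BRD4 peaks at their observed shares but independently of each other, 40.8% would hold both. That figure does not allow for the width of BRD4 peaks, and wider peaks have more room for both. Of the other BRD4 peaks, 18.9% overlapped LSD1 alone, 4.51% MTA3 alone and 24.0% neither. Peaks with both partners had a median width of 1185 bp and a median fold enrichment of 8.38, against 334 bp and 3.96 for peaks with neither. They lay at gene ends in 49.4%, in gene bodies in 31.4% and between genes in 19.1%. The highest BRD4 enrichment with both partners, 144.6-fold, was on chromosome X at 115732229 to 115733708, 81367 bp from PLS3. Others were on chromosome 2 at 206083478 to 206087215 within INO80D, a subunit of a chromatin remodeller (91.4-fold), and on chromosome 17 at 7883878 to 7889669 across NAA38 and CHD3 (82.4-fold). Within 20 kb of ESR1 (chromosome 6, 151656672 to 152129619) there were 27 BRD4, 51 LSD1, 44 MTA3 and 80 H3K4me1 peaks. XBP1 had 7, 10 and 13 peaks of BRD4, LSD1 and MTA3, GATA3 13, 16 and 19, PELI1 1, 2 and 2, GNA13 7, 16 and 12, and PDPK1 5, 4 and 4.

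The lists labelled H3K27ac and RNAPol2 were compared with expression, since the super-enhancers rest on the former. ESR1, expressed in MCF-7, had 1 peak labelled H3K27ac and 0 labelled RNAPol2 within 20 kb, while VIM had 10 and 3, with a RNAPol2 fold enrichment of up to 182, and AXL had 13 and 6. VIM and AXL are below 1 FPKM in untreated MCF-7. Other luminal genes had peaks of both lists, with 9 and 12 at GATA3, 2 and 3 at XBP1 (up to 95.1-fold for RNAPol2), 14 and 2 at SPDEF, 3 and 3 at FOXA1 and 7 and 1 at KRT19. BRD4 peaks lay at a gene end of 81.4% of 274 genes restricted to MCF-7 and 42.2% of 256 restricted to MDA-MB-231 (Fisher's exact test, adjusted p 3.115e-20). For LSD1 these shares were 77.0% and 45.3% (1.265e-13), for MTA3 72.3% and 39.8% (1.265e-13) and for H3K4me1 89.4% and 64.5% (8.212e-12). The list labelled H3K27ac marked 73.0% and 79.3% (0.1032), and that labelled RNAPol2 46.0% and 65.2% (1.399e-05), lower in genes restricted to MCF-7. At 2021 genes silent in both lines the last 2 lists marked 31.5% and 16.7%, and BRD4 18.2%.

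**Figure D3:**
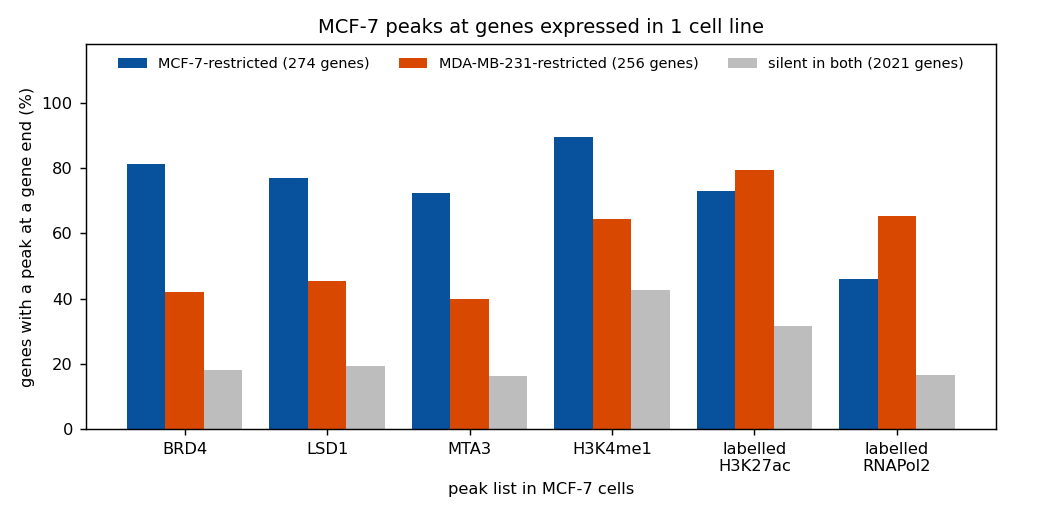
Share of genes (%) with a peak at a gene end in each of 6 peak lists deposited as MCF-7, for 274 genes restricted to MCF-7, 256 restricted to MDA-MB-231 and 2021 silent in both. The share was higher in MCF-7-restricted genes for BRD4 (81.4% and 42.2%) and lower for the list labelled RNAPol2 (46.0% and 65.2%).

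Super-enhancers ask whether the factors gather at long stretches of acetylated chromatin, with the caveat that the list labelled H3K27ac did not favour MCF-7 genes. Of 18619 stitched regions, 814 were super-enhancers, with a median length of 61244.5 bp against 2102 bp. BRD4, LSD1 and MTA3 lay together in 71.4% of super-enhancers (581) and 18.5% of other regions (3301, odds ratio 11). Per Mb of region, however, super-enhancers held 49.9 BRD4 peaks and other regions 60.1 (ratio 0.831), with 59.6 and 134 Mb covered. For LSD1 the ratio was 0.864 and for MTA3 0.825. The highest was on chromosome 12 at 75622670 to 76006833, 18613 bp from PHLDA1, which fell with JQ1 in MCF-7 (20.7 ± 7.57 to 8.80 ± 3.22 FPKM). Next came chromosome 8 at 127835481 to 128003424, 92529 bp from MYC, with 20 BRD4, 38 LSD1 and 18 MTA3 peaks. Also next to the 10 highest, ME3, TGFB2 and ERRFI1 were at 0.805 ± 0.148, 1.92 ± 2.37 and 11.8 ± 3.38 FPKM in MCF-7 and at 16.9 ± 5.06, 17.2 ± 1.82 and 128 ± 51.7 in MDA-MB-231, while SLC39A11 was at 22.5 ± 0.106 and 6.83 ± 1.44 and GNG7 at 1.03 ± 0.226 and 0.820 ± 0.0990. Near lower-ranked super-enhancers, CD44, PPARG, IRS1 and ABCC3 fell in MCF-7 and ATF3, ITGA6 and LOXL2 rose. Stitching BRD4 peaks in place of the list labelled H3K27ac gave 349 regions, of which 98.9% held all 3 factors, against 57.6% of the rest. Their median length was 25055 bp against 747.5 bp, and per Mb they held fewer BRD4, LSD1 and MTA3 peaks than the rest (ratios 0.513, 0.587 and 0.602). Every region was built from BRD4 peaks and gaps count as length, so these ratios cannot tell whether the factors gather either.

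The last comparison asks whether genes bound by the 3 factors responded to JQ1. Of 9016 genes with a co-occupied site at a gene end, 18.2% fell in MCF-7 against 15.7% of other genes (odds ratio 1.2, Fisher's exact test, adjusted p 0.001768), and 1127 rose (odds ratio 1.14, adjusted p 0.08202). In MDA-MB-231, for which there are no peaks, 18.2% of these genes fell against 16.8% (adjusted p 0.09564). For 626 genes with BRD4 alone the shares that fell were 17.4% and 17.4% in MCF-7 (adjusted p 1) and 15.3% and 17.9% in MDA-MB-231 (adjusted p 0.1611). For 673 genes near super-enhancers of the list labelled H3K27ac they were 19.9% and 17.3% in MCF-7 (adjusted p 0.146) and 24.1% and 17.4% in MDA-MB-231 (odds ratio 1.5, adjusted p 0.0003104). Camera called none of these 6 sets (adjusted p 0.4081 to 0.9784, none at an unadjusted p below 0.05, lowest 0.06802), and with an estimated correlation each had an adjusted p of 0.988. Against 10000 random sets of genes with similar expression, the median of co-occupied genes in MCF-7 (-0.06) was below all, that of super-enhancer genes (-0.13) below all but 0.17%, and that of super-enhancer genes in MDA-MB-231 (-0.24) below all. The random sets were drawn from all 13219 tested genes, bound ones included, and treat genes as independent. For the 9016 co-occupied genes they therefore held largely the same genes. Their medians in MCF-7 lay in a narrow range (95% from -0.0492 to -0.0334, middle -0.0420), so being below all reflects a small gap. The median of co-occupied genes in MDA-MB-231 was at percentile 11.5 of such sets, and those of genes with BRD4 alone at 46.3 in MCF-7 and 95.3 in MDA-MB-231. Co-occupied genes had a higher mean expression than others, at 3.68 and 2.86 on the log2 scale.

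Super-enhancers of stitched BRD4 peaks, whose nearby genes were tested as a choice made after the data were seen, gave a different set of 230 genes, of which 66 were in the set above. Of these, 80 fell and 11 rose in MCF-7, where 34.8% fell against 17.1% of other genes (odds ratio 2.58, Fisher's exact p 1.812e-10). The mean change was -0.59 against -0.09 (camera adjusted p 0.0007881, adjusted p = 0.2334 with an estimated correlation). GREB1, UGT1A6, XBP1, MYB, ESR1, CD44, MYC, BCL3, ABCC3 and MTA3 were among those that fell, and ACSL3, an acyl-CoA synthetase, rose. In MDA-MB-231, 19.1% fell against 17.7% (Fisher's exact p 0.6013). The set was chosen by BRD4 peaks of MCF-7, and some of its genes had little or no room to fall in MDA-MB-231. UGT1A6 was at 0 FPKM there, and GREB1 and ESR1 were low. The shares of the 2 lines therefore do not show a response particular to MCF-7. Random sets matched for expression were not drawn for these genes.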

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

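The tests of cells other than MCF-7, of histone RNA without poly(A) and of a floor in MCF-7 were chosen after the result they address was seen. What singled out the differences below is a test of the difference between the JQ1 effects of the 2 lines (MDA-MB-231 minus MCF-7), by limma for genes, where 590 were past the threshold, and by camera for lists.

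The lists labelled H3K27ac and RNAPol2 marked the ends of genes active in MDA-MB-231 alone at least as often as those of genes active in MCF-7 alone. The shares differed by -19.2 percentage points for RNAPol2 and -6.30 for H3K27ac, against 39.2 in the other direction for BRD4, so cells other than MCF-7 behind these 2 libraries stay open as an explanation. Low sensitivity of the RNAPol2 library is argued against by the 48.5 points between MDA-MB-231-restricted and silent genes, and a loose peak threshold by the -14.3 points that remained in its 10000 strongest peaks. A biological explanation, that MCF-7 chromatin carries these marks at genes without RNA in this cell line, was not tested.

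Histone genes rose (53 of 60 in MCF-7, 27 of 60 in MDA-MB-231, where 1 fell) while replication genes fell. Histone RNA without poly(A), carried over into the JQ1 libraries, cannot be told apart from a change of the list's own histones in MDA-MB-231 and stays open in MCF-7. Over all 60 the list's median exceeded that of others by 3.53 in MDA-MB-231 (permutation p 0.0003), where 12 of the others are at 0 in all libraries of the line, but among histones of at least 2 FPKM without JQ1 by 2.34 (7 and 11 genes, permutation p 0.312), where the summed FPKM rose 8.62-fold and 9.36-fold, and by -0.0801 in MCF-7 (permutation p 0.894). The summed FPKM of all histone genes rose 4.26-fold in MCF-7 and 8.86-fold in MDA-MB-231. This argues against a mere shift of reads from some near-identical copies to others. It cannot tell how many copies rose, since reads of a rising copy may also be listed under others, and H2AC18 and H2AC19 carry identical values. Scaling of the libraries is argued against by the list's lowest median over 3 scalings and 2 lines, 2.32, and an effect of JQ1 itself on histone RNA stays open and untested.

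The mitosis list fell further in MDA-MB-231, with a median difference of -2.57 (camera adjusted p 6.512e-33, adjusted p = 0.3242 with an estimated correlation). Scaling of the libraries is argued against by the median nearest 0 over 3 scalings, -2.48, and a single library by the median nearest 0 with 1 library left out, -2.22 (without MDA-MB-231 DMSO replicate 2). A floor reached in MCF-7 is argued against by the list's median of 15.1 FPKM in its JQ1 libraries, above the 5.67 FPKM reached in MDA-MB-231 with JQ1. A difference between the cell lines in their response stays open, and the media differ with the lines.

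Other lists also differed between the lines by camera with its preset correlation, with median differences of 0.96 for oestrogen response, 1.5 for HEXIM1 and histone genes, 0.67 for interferon-stimulated genes, -0.67 for mesenchymal markers and -0.83 for DNA replication. None was called with an estimated correlation (in that order, adjusted p = 0.3242, 0.4557, 0.8682, 0.3242 and 0.5912 with an estimated correlation). The interferon call also ended without MCF-7 DMSO replicate 2, MDA-MB-231 DMSO replicate 1 or JQ1 replicate 2 (adjusted p 0.3465, 0.06027 and 0.1004, in a range from 3.186e-05), and the mesenchymal call without MDA-MB-231 DMSO replicate 1 (0.06027, in a range from 0.001958 to 0.07084). Where both JQ1 libraries lay beyond both DMSO libraries in each line, genes with the largest positive differences were PEG10 (4.22), MT1A (3.90), SYTL5 (3.89), AQP3 (3.37), DHRS2 (3.29) and CALCR (3.29). Those with the largest negative differences under the same condition were NGFR (-4.12), ADGRF1 (-4.01), CSF3 (-3.71), H4C12 (-3.49), CDC20 (-3.45) and CDCA8 (-3.38).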

How the results depend on the processing

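Shuffles within H3K4me1 peaks alone and the test of genes near super-enhancers of stitched BRD4 peaks were added after the data were seen. Of 948 comparisons of named genes with an alternative, 919 kept their direction and side of the threshold and 29 missed it, and of 1209 for gene lists 1102 did, with 61 lost and 46 gained calls. Without the estimated correlation and fry these were 916 of 961, with 15 lost and 30 gained. No call of a named gene or gene list turned its direction. The 2352 comparisons in all also include 195 of counts, shares and sets of bound genes, and counts and shares have no direction to turn. The majority among calls for the difference turned without MCF-7 DMSO replicate 1 or 2. Lists without a call changed sign in 67 comparisons and sets of bound genes in 5. The difference to other genes went from 0.01 to -0.02 at -log10 q of at least 5 and to -0.01 without MDA-MB-231 JQ1 replicate 1 for co-occupied genes in MDA-MB-231, and from -0.00201 to 0.03 without MCF-7 JQ1 replicate 2 and to 0.00903 without DMSO replicate 1 for genes with BRD4 alone in MCF-7. For those in MDA-MB-231 it went from 0.06 to -0.00471 with gene ends of 10 kb. With quantile normalization the share that rose among called genes passed 50% in MCF-7 (51.6%), in MDA-MB-231 (52.5%) and among shared genes (55.7%). Leaving a library out makes the lone library of its group one assumed to vary like the other groups. The cause was not tested for the values below, except where fewer libraries or peaks or a larger minimum change define the alternative. FPKM hold no counts, so what the depth of the libraries limits is unknown.

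With a change of at least 2-fold the calls were 1969 in MCF-7, 1926 in MDA-MB-231, 4085 between the untreated lines and 800 shared, against 3900, 3707, 6704 and 1923. MDA-MB-231 alone gave 1127, and the difference with 0.1 added gave 379 (590 with 1). Without 1 library the calls ranged from 1363 (MCF-7 JQ1 replicate 1) to 2454 (JQ1 replicate 2) in MCF-7, and from 2070 (MDA-MB-231 JQ1 replicate 1) to 3965 (DMSO replicate 1) in MDA-MB-231. They ranged from 179 (without MCF-7 JQ1 replicate 1) to 834 (without MDA-MB-231 DMSO replicate 1) for the difference, from 723 to 2106 for shared genes without the same 2 libraries, and from 4806 to 6257 between the untreated lines. The replicate block by title tag gave 1475 calls for the difference, 2945 shared, 5385 in MCF-7 and 5162 in MDA-MB-231. In their titles 3 of the 4 pairs share a tag, and the remaining MCF-7 pair shares the tag N in its column names. Between libraries of a tag, deviations from the group means correlated at 0.447 in MCF-7 and 0.481 in MDA-MB-231. No label states that these libraries were paired, and the main fit does not pair them. Under the block the hypoxia list was called in MCF-7 and in the difference, apoptosis in MDA-MB-231 and in the difference, and the unfolded protein response in MDA-MB-231. Of the 93 list results and 60 named genes it could be run for, which leave out the untreated lines, no other changed its call.

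Lists called with an estimated correlation were 0 in MCF-7, 0 in MDA-MB-231, 0 for the difference and 1 between the untreated lines, against 9, 9, 6 and 10, and fry called 3 for the difference and 16 between the lines. Without 1 library they ranged from 9 to 10, 8 to 10, 4 to 12 (12 without MDA-MB-231 DMSO replicate 2) and 7 to 11. Apoptosis was also called in MDA-MB-231 after quantile normalization (0.0302). Calls gained without 1 library were those of hypoxia and p53 in MCF-7, apoptosis and the unfolded protein response in MDA-MB-231, NF-kB, Wnt, hypoxia, drug metabolism, antigen presentation, apoptosis, ribosome, unfolded protein response and cholesterol genes for the difference, and replication and hypoxia between the untreated lines (adjusted p 7.819e-05 to 0.04896).

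With -log10 q of at least 5 there were 28677 BRD4, 43055 LSD1 and 20165 MTA3 peaks, and 62612 and 48479 in the lists labelled H3K27ac and RNAPol2; the strongest 10000 of each of the 6 lists were also used. BRD4 peaks overlapped LSD1 in 67.8% when 0.5 of the smaller peak had to be shared, 71.1% at that q and 28.94% among the strongest, and MTA3 in 54.1%, 48.4% and 44.7%. MTA3 peaks overlapped LSD1 in 78.3%, 85.1% and 43.75%, and BRD4 the list labelled H3K27ac in 54.5%, 64.0% and 62.1%. Co-occupancy was 49.3% with that share, 43.4% at that q and 25.04% with summits within 250 bp, and its ratio to shuffles within H3K4me1 peaks alone was 3.10. Super-enhancers with all 3 factors were 56.4% with gaps up to 5 kb, 65.03% ranked by length, 90.5% with all peaks stitched and 98.9% of 349 from BRD4 peaks. Genes near the last changed by -0.49 relative to others in MCF-7 (camera adjusted p 0.0007881, adjusted p = 0.2334 with an estimated correlation), where those of the list labelled H3K27ac ranged from -0.13 to -0.04 without 1 library. The other sets of bound genes ranged from -0.04 to 0.03 in MCF-7, from -0.01 to 0.10 for co-occupied and BRD4-only genes in MDA-MB-231, and from -0.24 to -0.08 near super-enhancers there.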

Other observations

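The genes and neighbourhoods in this part were picked after their values were seen, and none has a test beyond the fit of all genes.

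Some metallothionein and ferritin genes rose in MDA-MB-231, while MT1F was at 4.52 ± 2.29 and 4.56 ± 1.2 FPKM (adjusted p 0.938). MT1X, a metallothionein, rose from 117 ± 67.7 to 1216 ± 532 FPKM (3.42, adjusted p 0.004067) and MT2A by 1.62 (adjusted p 0.009979). FTL, the light chain of ferritin, rose from 2725 ± 1582 to 14805 ± 5631 (2.52, adjusted p 0.005139) and in MCF-7 from 830.3 ± 240 to 2411 ± 39.4 (1.57, adjusted p 0.03023). TUBB3, a tubulin of neurons, rose in MDA-MB-231 from 75.2 ± 10.3 to 1048 ± 244 (3.77, adjusted p 0.0002619) and was at 70.1 and 141 in MCF-7 (adjusted p 0.05896). TXNIP, an inhibitor of thioredoxin and glucose uptake, rose in MDA-MB-231 from 59.0 ± 9.93 to 363 ± 60.1 (2.60, adjusted p 0.007864). The cell cycle inhibitor CDKN1A rose there from 94.1 ± 59.0 to 274 ± 39.7 (1.68, adjusted p 0.02922). BRCA1, which repairs DNA breaks, fell in both lines, from 8.35 ± 0.0778 to 1.94 ± 0.262 in MCF-7 (-1.67, adjusted p 0.002175) and from 8.67 ± 2.59 to 0.945 ± 0.290 in MDA-MB-231 (-2.30, adjusted p 0.0005564).

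Some neighbouring genes were listed at or near 0 in every library of 1 line. In MDA-MB-231 these were 9 histone genes on chromosome 6 from 26216921 to 26273412, among them H2AC8 (mean 74.2 FPKM in MCF-7), and S100A12, S100A8, S100A7A and S100A7 on chromosome 1 from 153373711 to 153460651 (S100A8 35.3 in MCF-7). The means of H2AC8 and S100A8 pool the MCF-7 libraries without and with JQ1. HOXA1 to HOXA11 on chromosome 7 from 27092993 to 27185232 were at 0.02 FPKM or less in MDA-MB-231, while in MCF-7 HOXA10 fell from 6.64 ± 0.0990 to 1.61 ± 0.983 (-1.60, adjusted p 0.003388). In MCF-7 6 genes of the MAGEA and CSAG families on chromosome X from 152714586 to 152769689 were at 0.05 or less. The highest of them, MAGEA6, was at 55.04 and 32.52 in replicate 2 of MDA-MB-231 without and with JQ1 but at 0.15 and 0.08 in replicate 1.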
